A study of Homo sapiens with 12 samples.

How the data were processed

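RNA from 12 samples of the MDA-MB-231 line was measured on Illumina expression BeadChips, in 6 groups of 2 by line (mock, tRNA-Arg, tRNA-Glu) and time of α-amanitin (0 or 9 h). Groups were taken from the sample labels. The deposited non-normalized table holds an intensity for each of 47231 probes per array, not normalized per the file headers. The authors' processed values, deposited as the series matrix, are intensity values on a linear scale. They appear quantile normalized between arrays, with medians of 56.2 to 56.3. The labels name lumi among the authors' tools without a version or step. Other steps of the authors are not given in the sources used here. The authors' deposited table of stability holds a score per gene for each tRNA line against control, whose formula, scale and log base are not stated. The non-normalized table also has 12 per-sample columns of deposited detection p-values (p_value), headed by a chip position that names no sample. They were not used.

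The design fixed before the data were examined named a background and a filter from detection p-values. A first version assigned those 12 columns to arrays by their values, and it was set aside because their names match no sample. The background and the filter used instead were therefore chosen after that version's counts had been seen. They are limma's normexp correction (saddle-point method, offset 16) estimated from each array's own intensities, then quantile normalization and log2. A probe was tested if its raw intensity was above the array's median, called the floor, on both arrays of at least 1 group. This kept 25456 probes, 17810 of which were above the floor on all 12 arrays.

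All 12 arrays entered 1 limma fit of the 6 group means without covariates, followed by contrasts and empirical Bayes moderation (6 residual and 7.06 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg within each contrast at 0.05. There were 10 contrasts: the amanitin response in each line and over the 3 lines, the lines against each other at 0 h, and stability. Stability is the 9 h minus 0 h change in one line minus that in another. The median half-width of the 95% confidence interval was 0.17 on the log2 scale for the mean amanitin response, 0.30 at 0 h and 0.42 for stability. On simulated data, changes of 1 on the log2 scale were recovered in 100% of probes for the mean amanitin response, 97.0% for tRNA-Glu at 0 h and 61.2% for tRNA-Glu stability. Changes of 0.5 were recovered in 98.5%, 29.9% and 2.99%, so stability differences of that size would mostly go uncalled under those settings. The simulation changed few probes (67 of 25456 at that size) and gave each probe independent noise of equal spread in every group. Recovery in the real data can differ.

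Probes were not mapped to genes, so they are given by identifier: up to 2 with the largest and 2 with the smallest change among called probes whose groups do not overlap, or the 2 smallest p-values each way where fewer than 5 were called. The fixed rule named more genes per contrast by symbol, and matching probes to the authors' genes by value was tried and gave no usable map. For the same reason the planned choice of 1 probe per gene, the set test on the arrays and the codon content test were not run, and the genes EXOSC2 and GRIPAP1 were read only from the authors' deposited table. The over-expressed tRNAs themselves were not measured by name here. Some items, among them the values of 1 gene list, are not reported here.

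The 19 gene lists and EXOSC2 and GRIPAP1 were fixed at the same stage as the design. In the authors' deposited table each list's median was ranked among medians of 10000 random lists of the same size. This replaced the set test after the table had been seen. Other backgrounds, chosen after seeing the data, were the genes of the fixed lists, genes without placeholder names (such as LOC numbers), and genes matched on the size of the score in the other line. Random lists could not be matched on expression, which the authors' deposited table does not hold. From the authors' deposited table the text names the 10 highest and lowest symbols as a pool and, in each list, members among the 4 with the largest scores in size for either line, since it has no p-values. Count of members adjusted over the list alone could not be made from scores without p-values.

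The correlation expected from shared mock arrays was simulated with 100 draws of unchanged groups, with independent noise for each probe and array. Raw intensity between times was compared by an exact permutation test. Replicate numbers did not pair the samples: residuals of the same number correlated at -0.256 to 0.0859 over 15 pairs of groups. Alternatives changed the background, normalization, filter, groups in the fit, replicate block, array weights, time points and offset, used the authors' processed values, and left out each array in turn. The tools were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.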

Results

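MDA-MB-231 is a human breast cancer cell line of the triple-negative, mesenchymal type. The study over-expressed 1 of 2 transfer RNAs in it, a tRNA-Glu or a tRNA-Arg, beside a mock line. Cells were treated with α-amanitin, which blocks RNA polymerase II, at 10 µg/mL for 0 or 9 h. With new mRNA synthesis blocked, the amount of an mRNA left at 9 h relative to 0 h reflects how fast it decays. The title question was how these tRNAs affect mRNA stability. Total RNA was labelled with biotin and hybridised to Illumina expression BeadChips, giving 12 arrays in 6 groups of 2 (3 lines by 2 times). The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples. With 2 arrays per group, the number of arrays limits the precision.

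The mean non-normalized intensity per array was 573 ± 27.3 (SD, n = 6) at 0 h and 512 ± 12.2 (SD, n = 6) at 9 h. A two-sided exact permutation test gave p = 0.00216, the smallest its splits allow. The 75th percentile of intensity was 192.5 ± 17.6 (SD, n = 6) at 0 h and 143 ± 6.38 (SD, n = 6) at 9 h. The first principal component of the log2 signals held 63.2% of the variance and separated the 2 times. The second held 8.82%, with tRNA-Glu 0 h replicate 1 at -30.1 and the other 0 h arrays between 0.903 and 10.7. That array also had the highest 75th percentile, 224.55. At 9 h the second component ran from mock (-17.9 and -14.4) through tRNA-Arg (0.562 and 4.99) to tRNA-Glu (10.9 and 12.7). The third component held 7.45%, with all mock arrays between 12.7 and 20.5 and all tRNA arrays between -19.5 and -4.62.

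**Figure D1:**
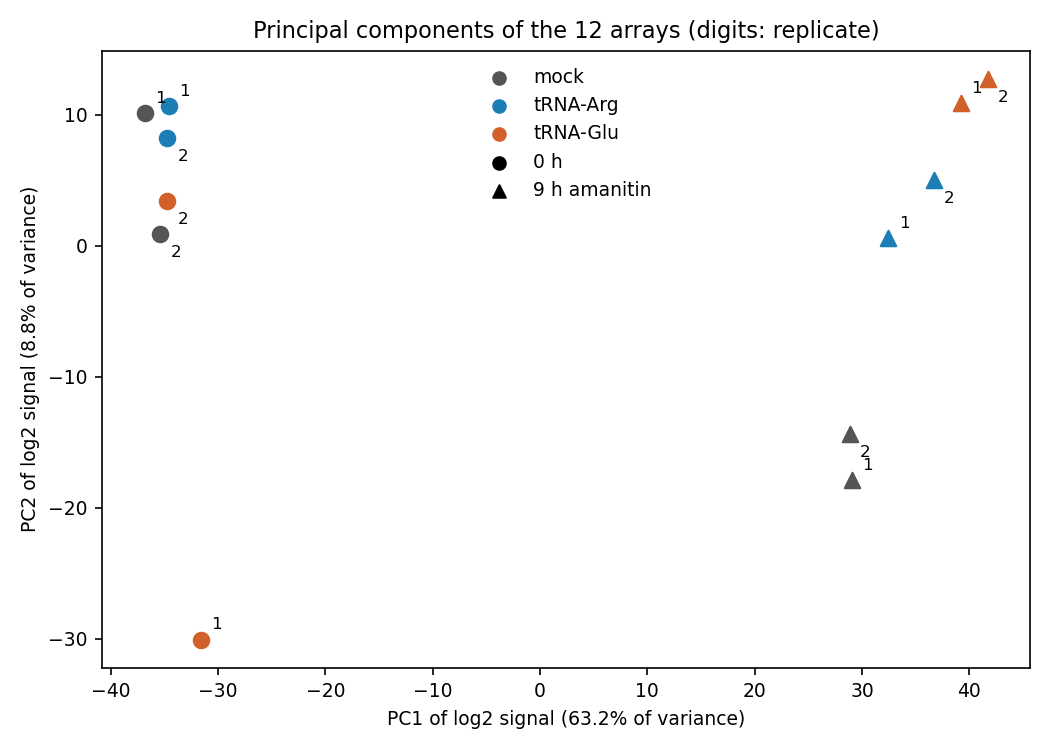
Each point is 1 of the 12 arrays on the first (horizontal) and second (vertical) principal component of log2 signal, coloured by line, with circles for 0 h and triangles for 9 h. The first component, 63.2% of the variance, parts 0 h from 9 h, and tRNA-Glu 0 h replicate 1 lies at -30.1 on the second.

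The mRNAs with the most extreme stability scores in tRNA-Glu against control cells were read by gene name from the authors' deposited table. It holds no p-values, so the genes named are extremes of a ranking and none was tested. The authors' deposited table gives a signed stability score per gene and line. Its formula, scale and log base are not stated, and its direction is taken from its header, so a positive score is read as more stable in the tRNA line. In the authors' deposited table the tRNA-Glu scores of 34602 genes had a central 95% of -0.294 to 0.283. Their SD was 1.59 times that of the tRNA-Arg scores in the authors' deposited table, so the size of a score does not compare directly between the lines. No score per replicate is given in the authors' deposited table, so the weight in it of tRNA-Glu 0 h replicate 1, the array that lay apart, is not known here. The lowest named score for tRNA-Glu in the authors' deposited table was that of CAPG, an actin-capping protein, at -1.41. NOMO3 followed at -1.23 and PDIA6, a disulfide isomerase of the endoplasmic reticulum, at -1.17 in the authors' deposited table. VOPP1 had -1.10 there, and its older symbol ECOP, listed apart, had -1.04 in the authors' deposited table. The splicing factor HNRNPL had -1.05, the retinol saturase RETSAT -1.05 and S100A16 -0.924 in the authors' deposited table. At the other end among named genes, AMY1C had 1.25, RPL21 1.14, ERH 0.948 and RPL26 0.944 in the authors' deposited table. RN7SK, an RNA made by polymerase III that holds the elongation factor P-TEFb inactive, had 0.844 in the authors' deposited table. ADI1, an enzyme of methionine salvage, had 0.766 and RANBP9 0.737 in the authors' deposited table. AMY1C, RPL21, NOMO3 and HLA-H (-1.01 in the authors' deposited table) have near-identical copies in the genome, so a probe may not separate them.

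Cell cycle genes made up the lowest of the 19 fixed gene lists for tRNA-Glu in the authors' deposited table, with a median score of -0.195 over 46 genes. Of these, 24 were in the lowest 5% of all genes, 2 were in the highest 5% and 11 were above 0 in the authors' deposited table. The lowest were UHRF1 at -0.722, the replicative helicase subunit MCM2 at -0.634, TK1 at -0.622 and KIF2C at -0.533 in the authors' deposited table. Of the members largest in size for tRNA-Arg, RRM2 had -0.521 and the mitotic kinase PLK1 went the other way at 0.519 for tRNA-Glu in the authors' deposited table. Ribosomal protein genes had a median of 0.0973 over 77 genes, with 57 above 0, 30 in the highest 5% and 11 in the lowest 5%, in the authors' deposited table. Beside RPL21 and RPL26, RPL35A had 0.626 and RPL24 0.615 in the authors' deposited table. Transcripts of other polymerases, which amanitin at this dose is not directed at, had a median of 0.269 over 13 genes, 12 of them above 0, in the authors' deposited table. With their synthesis not the target of the block, the scores of these transcripts need not reflect decay. Among them RNU6-1 had 0.599, BCYRN1 0.561 and RNY3 0.321 in the authors' deposited table. Oxidative phosphorylation genes had a median of 0.0380 over 64 genes, with ATP5E at 0.542, COX6C at 0.429, UQCRH at 0.427 and SDHA at -0.365, in the authors' deposited table.

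Glycolysis and cholesterol synthesis lay lower for tRNA-Glu: medians were -0.0409 over 18 genes and -0.0616 over 25 genes in the authors' deposited table. PGAM1 had -0.723, PKM2 -0.672 and LDHB 0.256, and of the sterol enzymes EBP had -0.671, SC5DL 0.360 and FDPS 0.326, in the authors' deposited table. Genes of the RNA exosome and mRNA decay had a median of -0.0287 over 55 genes, with LSM4 at -0.848, EXOSC4 at -0.615 and LSM5 at 0.375, in the authors' deposited table. ZNF genes had a median of -0.00916 over 525 genes, and ZNF223 stood out at 0.718, in the authors' deposited table. These 8 lists, 3 above and 5 below, were outside the central 95% of 10000 random lists of equal size in the authors' deposited table. Over both lines 18 of 38 medians were outside in the authors' deposited table. Random lists treat genes as independent, whereas genes of a list vary together and both lines are scored against the same control, so no number expected by chance is given for the authors' deposited table. With random lists drawn only from the 598 genes of the fixed lists, 4 of the 7 tRNA-Glu lists that could be compared stayed outside: cell cycle, ribosomal proteins, other polymerases and oxidative phosphorylation, all from the authors' deposited table. The glycolysis, cholesterol and exosome and decay lists for tRNA-Glu did not, and with means the cholesterol and the exosome and decay lists were inside, in the authors' deposited table. Glycolysis was also inside for tRNA-Glu without placeholder names or with matched genes in the authors' deposited table.

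The other 11 lists were inside that range for tRNA-Glu in the authors' deposited table, though single members lay far out. The stress-response gene DDIT4 had -0.834 and the glutamine carrier SLC1A5 -0.386, in a list with a median of -0.0237, in the authors' deposited table. The seryl-tRNA synthetase gene SARS had -0.829 and CARS -0.478, while the synthetase list had a median of 0.0131, in the authors' deposited table. Immediate early and AU-rich mRNAs had a median of 0.0245, with JUN at 0.528, IL8 at 0.506, PLK2 at 0.503 and ZFP36L2 at -0.543, in the authors' deposited table. Metastasis genes had a median of -0.0222, with S100A4 at 0.544 and PLAUR at -0.415, in the authors' deposited table. Mesenchymal markers had a median of -0.0205, with SNAI2 at -0.463, in the authors' deposited table. Luminal markers had 0.000911 with KRT19 at -0.748, and basal markers 0.0239 with SFN at -0.666, in the authors' deposited table. Heat shock genes had -0.0201 with DNAJB1 at -0.482 and HSPA1A at 0.333 in the authors' deposited table. Interferon genes had -0.00789 with IFI35 at 0.453 and IFIT3 at -0.332, and histone genes 0.0156 with HIST1H4C at -0.361 and HIST1H2BK at 0.354, in the authors' deposited table. With means in place of medians, 6 of these 11 lists were outside for tRNA-Glu: histone genes above, and stress response, synthetase, mesenchymal, basal and heat shock genes below, in the authors' deposited table. Median and mean differed in sign for the immediate early, synthetase, luminal and basal lists for tRNA-Glu in the authors' deposited table. EXOSC2 and GRIPAP1, both targets this study is known to have followed, had 0.195 and -0.114 for tRNA-Glu in the authors' deposited table. These were at percentiles 94.6 and 9.82 of all genes, both inside the central 95% of the scores, in the authors' deposited table.

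**Figure D2:**
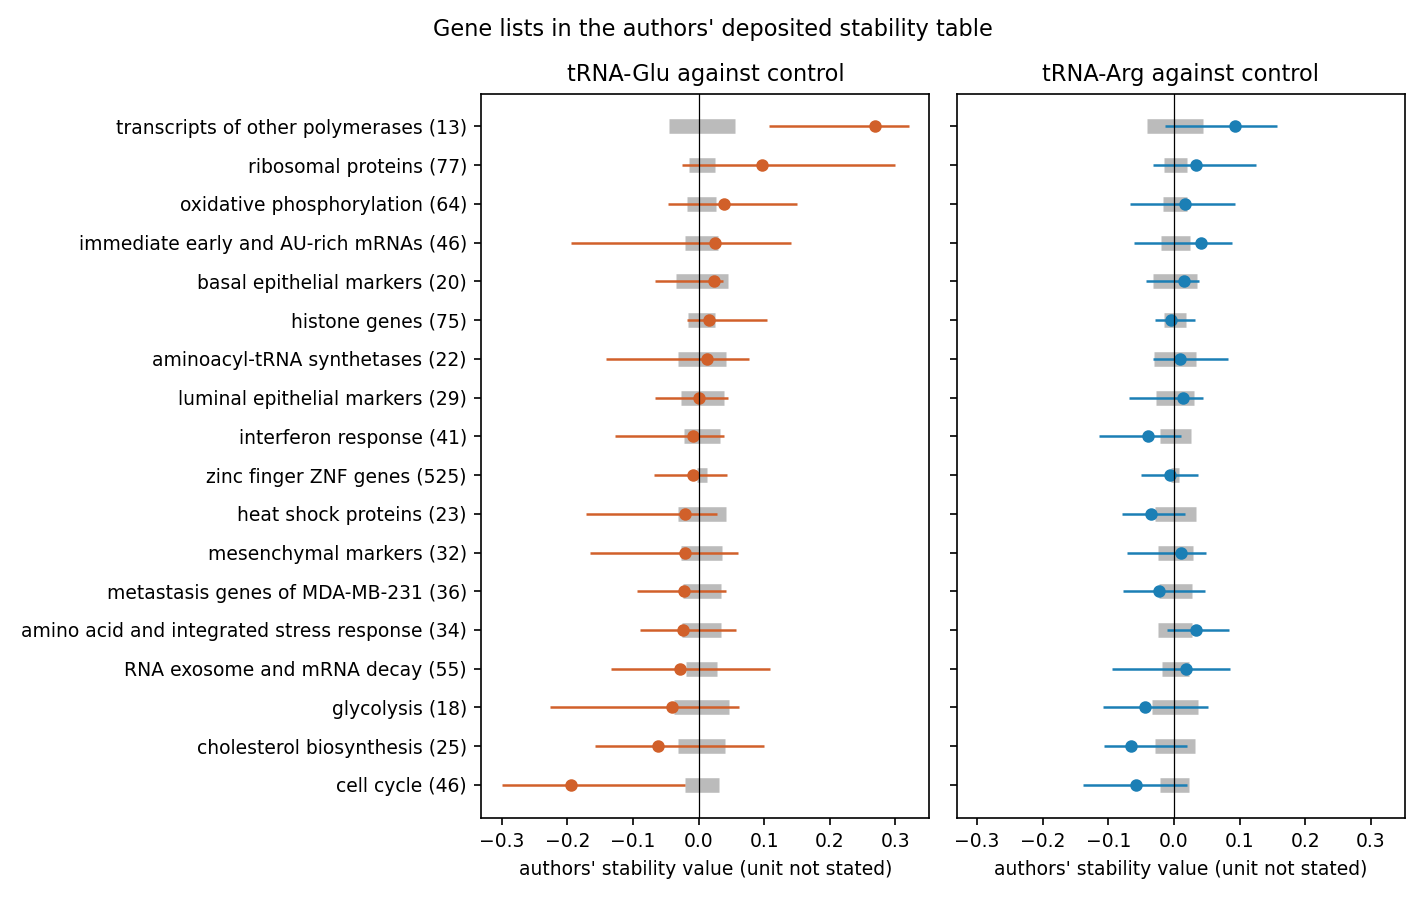
Medians (points) and middle 50% (thin lines) of the authors' stability score in 18 of the gene lists, for tRNA-Glu (left) and tRNA-Arg (right), with the number of genes in parentheses; grey bars are the central 95% of medians of 10000 random lists. In the authors' deposited table the cell cycle list is at -0.195 for tRNA-Glu and -0.0573 for tRNA-Arg, left of the grey bar in both, the tRNA-Glu scores having 1.59 times the SD of the tRNA-Arg scores.

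On the arrays, the tRNA-Glu stability difference is the change from 0 to 9 h in tRNA-Glu cells minus that in mock cells, tested per probe with limma. A single probe of 25456 passed an adjusted p of 0.05. More probes passed without background correction, with median scaling and with the authors' processed values, and fewer with array weights, as given below. ILMN_3268697 had a log2 difference of 2.94 (SE 0.30, adjusted p 0.00557), and all its tRNA-Glu changes lay above all its mock changes. Its mean log2 signal went from 7.79 to 7.05 in mock cells, from 7.20 to 7.42 in tRNA-Arg cells and from 6.59 to 8.78 in tRNA-Glu cells (2 arrays each). The next probes by p were ILMN_2074860 at 1.29, ILMN_1774826 at -1.54 and ILMN_1753567 at -1.25, each with an adjusted p of 0.0592. At an unadjusted p of 0.05 there were 4395 probes, where chance gives 1272.8. Differences from sets of arrays with none in common correlated across probes between 0.278 and 0.458 over 8 ways of forming the sets, probes not being independent replicates. The count of probes past an adjusted p of 0.05, 1 with all arrays, rested on single arrays, as given below. That count was highest without tRNA-Glu 0 h replicate 2, a fit that left only the array that lay apart in that group.

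**Figure D3:**
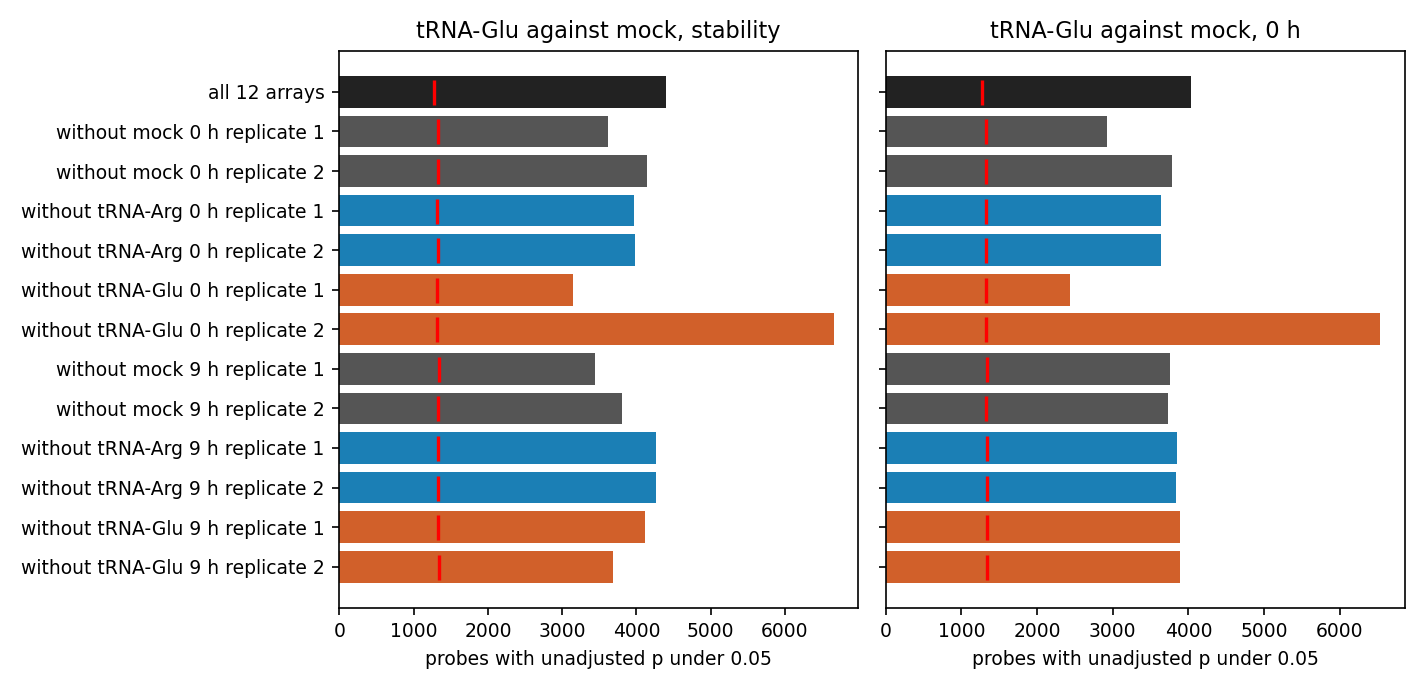
Bars give the number of probes with an unadjusted p under 0.05 (horizontal axis) for tRNA-Glu against mock in stability (left) and at 0 h (right), with all 12 arrays and without each in turn; red marks are 5% of the probes tested. With all arrays the bars reach 4395 and 4029, and without tRNA-Glu 0 h replicate 1 they reach 3144 and 2428.

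For tRNA-Arg, the lowest score in the authors' deposited table was that of ANKRD1, a transcriptional cofactor induced by YAP, at -0.857. The protease CTSD had -0.670, S100A16 -0.656, CAPG -0.656, and VOPP1 -0.621 in the authors' deposited table. The highest among named genes were ERH at 0.834, the RNA-binding protein TAF15 at 0.740, RPL21 at 0.716 and RN7SK at 0.644 in the authors' deposited table. EXOSC2 had 0.0177 and GRIPAP1 had 0.0447 for tRNA-Arg in the authors' deposited table. Cell cycle genes had a median of -0.0573 and cholesterol synthesis genes -0.0654, with EBP at -0.351, IDI1 at -0.315, SC5DL at 0.231 and INSIG1 at -0.207, in the authors' deposited table. Interferon genes had -0.0391, with IRF9 at -0.298 and IFIT2 at -0.214, in the authors' deposited table. Glycolysis genes had -0.0439, heat shock genes -0.0354 with HSPE1 at -0.306, and ZNF genes -0.00649, all below random lists in the authors' deposited table. Above random lists were other polymerases at 0.0934, immediate early mRNAs at 0.0412, ribosomal proteins at 0.0341 and the stress-response list at 0.0341 in the authors' deposited table. With random lists drawn from the fixed lists, glycolysis, heat shock and stress response were inside for tRNA-Arg, and 6 of 9 lists stayed outside, in the authors' deposited table. With means, those 3 and the immediate early list were inside for tRNA-Arg in the authors' deposited table. ZNF genes were inside for tRNA-Arg without placeholder names, and glycolysis with matched genes, in the authors' deposited table. Among immediate early mRNAs PLK2 had 0.477 and CYR61 0.322 for tRNA-Arg, but SOX4, the largest in size, had -0.561 in the authors' deposited table. In the stress-response list SLC7A5 had 0.229, whereas DDIT4 had -0.496 and SLC1A5 -0.241, the largest in size, in the authors' deposited table. The other 9 lists were inside, among them exosome and decay 0.0177 with EXOSC6 at -0.382, PATL1 at 0.377 and EXOSC8 at -0.275, oxidative phosphorylation 0.0170 and luminal 0.0140, in the authors' deposited table. Basal markers had 0.0153, mesenchymal 0.0109, synthetases 0.00984, histones -0.00453 and metastasis genes -0.0231 in the authors' deposited table. Median and mean differed in sign in 5 lists for tRNA-Arg: histone, exosome and decay, mesenchymal, luminal and basal, in the authors' deposited table.

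On the arrays, limma called 0 of 25456 probes for tRNA-Arg stability, with 1544 at an unadjusted p of 0.05 where chance gives 1272.8. The smallest p-values belonged to ILMN_1776535 at a log2 difference of 0.96, ILMN_1816990 at 0.96, ILMN_1690031 at -1.08 and ILMN_2340259 at -1.17, each with an adjusted p of 0.685. Differences from separate sets of arrays correlated across probes between 0.106 and 0.159 over 8 ways. The count of called probes moved when mock 0 h replicate 2 was left out, as given below. The 2 tRNAs also differed from each other by 0 probes with limma, with 2475 at an unadjusted p of 0.05, and the separate sets correlated between 0.147 and 0.233. The count of called probes between both tRNAs moved most without tRNA-Glu 0 h replicate 2, which left only the array that lay apart in that group. It also moved without tRNA-Arg 0 h replicate 1, tRNA-Arg 9 h replicate 1, tRNA-Glu 9 h replicate 1 or tRNA-Glu 9 h replicate 2.

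The scores of both tRNAs correlated across genes at 0.581 in the authors' deposited table, where both use the same control. CAPG, VOPP1, S100A16 and NOMO3 were among the lowest, and ERH, RPL21, RN7SK and AMY1C among the highest, for both tRNAs in the authors' deposited table, which the shared control can give without any effect of a tRNA. No value for unchanged groups was computed for the authors' deposited table. On the arrays the tRNA-Arg and tRNA-Glu stability differences correlated across probes at 0.590. Simulated unchanged groups sharing the mock arrays gave 0.499 (0.484 to 0.513 over 100 draws). The draws were independent for each probe, whereas probes of an array vary together, so real unchanged groups could spread wider. The observed value lay above all draws, but their range is too narrow to judge it. An effect common to both tRNAs therefore stays open.

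Before treatment, the same 4 probes differed most from mock in both tRNA lines. ILMN_1688335 was higher by 3.26 on the log2 scale in tRNA-Arg cells (SE 0.13, adjusted p 2.26e-08) and by 3.48 in tRNA-Glu cells (adjusted p 1.55e-08). ILMN_2088876 was at -3.10 in tRNA-Arg cells (adjusted p 2.26e-08) and at -2.91 in tRNA-Glu cells (adjusted p 5.15e-08). ILMN_2078430 was under the floor on both mock arrays and was at least 4.91-fold higher in tRNA-Arg cells and at least 5.71-fold higher in tRNA-Glu cells. ILMN_1775235 was at -2.25 in tRNA-Arg cells and -1.96 in tRNA-Glu cells. In all these the arrays of the groups did not overlap. On the 9 h arrays all 4 probes kept their direction. There ILMN_1688335 had a mean log2 signal of 6.17 in mock, 9.57 in tRNA-Arg and 9.88 in tRNA-Glu cells. Limma called 161 probes for tRNA-Arg (104 higher, 57 lower) and 203 for tRNA-Glu (118 higher, 85 lower). Of these, 56 were higher and 41 lower in both lines, though both use the same mock arrays. Differences from mock in sets of arrays with none in common correlated across probes at 0.278 and 0.312 for tRNA-Arg. For tRNA-Glu they correlated at 0.154 and 0.392, probes not being independent replicates. The counts of both lines moved widely with the processing, as given below. The differences of the 2 lines from mock correlated across probes at 0.614, and simulated unchanged groups sharing the mock arrays gave 0.487 to 0.516 over 100 draws. Those draws treated probes as independent, so their range is too narrow to judge the observed value. Between tRNA-Glu and tRNA-Arg limma called 0 probes, with 2420 at an unadjusted p of 0.05.

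At 0 h the tRNA-Arg count was 47 without mock 0 h replicate 1, 72 without mock 0 h replicate 2, 27 without tRNA-Arg 0 h replicate 1 and 43 without tRNA-Arg 0 h replicate 2. The tRNA-Glu count moved most without tRNA-Glu 0 h replicate 2, a fit that left only replicate 1, the array that lay apart, in that group. The deviation of that array cannot be told there from a line difference. The tRNA-Glu count also moved without tRNA-Glu 0 h replicate 1, mock 0 h replicate 1 or mock 0 h replicate 2. It was also 116 without tRNA-Arg 0 h replicate 1 or 2, 133 and 130 without mock 9 h replicate 1 and 2, 125 and 127 without tRNA-Arg 9 h replicate 1 and 2, and 131 and 132 without tRNA-Glu 9 h replicate 1 and 2. The count between both tRNAs moved most without tRNA-Glu 0 h replicate 2, with the same limit.

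Amanitin for 9 h gave the largest differences between groups on these arrays. Averaged over the 3 lines, ILMN_2188264 fell by 3.59 on the log2 scale, from 12.76 ± 0.24 to 9.17 ± 0.28 (SD, n = 6; limma adjusted p 5.97e-12). ILMN_2329914 fell by 3.45, from 10.47 ± 0.11 to 7.02 ± 0.34 (SD, n = 6; limma adjusted p 1.61e-11). ILMN_1881909 was higher by 2.55, from 10.09 ± 0.42 to 12.64 ± 0.30 (SD, n = 6; limma adjusted p 2.41e-10). ILMN_2211728 was higher by 2.22, from 6.14 ± 0.15 to 8.36 ± 0.15 (SD, n = 6; limma adjusted p 7.61e-11). Limma called 12413 probes, 48.8% of those tested, 7110 higher and 5303 lower after quantile normalization. Changes beyond 1 on the log2 scale were mostly losses, with 862 probes lower and 116 higher. Quantile normalization sets every array to the same distribution, so higher here means relative to the other probes. With median scaling the median of all probes was -0.07 in place of 0.05, and 2118 probes were higher and 7997 lower.

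By line, limma called 6866 probes in mock cells (3469 higher, 3397 lower), 7107 in tRNA-Arg cells (3517 higher, 3590 lower) and 8364 in tRNA-Glu cells (4272 higher, 4092 lower). In all 3 lines 3998 probes were called, 1488 higher and 2508 lower in each, with 2 in opposite directions. The responses correlated across probes at 0.861 for mock and tRNA-Arg, 0.746 for mock and tRNA-Glu, and 0.835 for tRNA-Arg and tRNA-Glu, the pairs having no array in common. The mock count was 4360, 4212 and 4374 without mock 0 h replicate 1, mock 9 h replicate 1 or mock 9 h replicate 2. The tRNA-Arg count was 4190, 4209 and 4150 without tRNA-Arg 0 h replicate 1, tRNA-Arg 0 h replicate 2 or tRNA-Arg 9 h replicate 2.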

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

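The tests of 1 array lying apart, of the background of the gene lists and of the immediate early list were chosen only after the results were seen, the bound of the last included. The other tests were written earlier, and their values were computed again after the background and filter had been replaced.

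Probe ILMN_3268697 stood out because its response to amanitin differed between lines, by 2.94 on the log2 scale between tRNA-Glu and mock cells, in the limma test of the difference itself. It was higher at 9 h than at 0 h on all tRNA-Glu arrays and lower on all mock arrays. No biological explanation was tested for this probe alone.

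The tRNA-Glu stability differences form a broad pattern, with unadjusted p-values under 0.05 in more than 5% of the probes tested but a single called probe. How far that excess lies beyond chance is not known, since probes vary together. The count of called probes moved widely with the processing, as given below. A single array, tRNA-Glu 0 h replicate 1, lies apart, and without it 3144 of 26407 probes had an unadjusted p under 0.05. That fit left a lone array in the tRNA-Glu 0 h group, which was assumed to vary like the other groups. With both arrays, this group had the largest replicate SD of the 6 groups, 0.202 on the log2 scale. The count of 3144 therefore cannot by itself decide whether that array is the whole source. In the comparison of sets of arrays with none in common, that array was never in both sets. If it were the whole source, the differences from those sets should not correlate across probes. They correlated between 0.278 and 0.458 over 8 ways, which argues against that array as the whole source. How much that array adds to the pattern stays open. A line difference should recur in separate arrays, and the lowest correlation over 8 ways was 0.278. A difference between the cultures or their handling would recur in the same way, so a tRNA effect and other line differences stay open. With 1 line per tRNA, the tRNA and the line are the same samples.

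The gene lists apart in the tRNA-Glu scores could reflect a deeper loss of short-lived mRNAs at 9 h in tRNA-Glu cells. The tRNA-Glu stability differences then should correlate above 0.1 with the tRNA-Arg amanitin response, which shares no array with them. The correlation was 0.0937 with all arrays and 0.166 without tRNA-Glu 0 h replicate 1, so this stays undecided. Of the lists outside the random range, 57.1% stayed outside when random lists came from the fixed lists alone, between the bounds set for unexpressed genes as the cause. The immediate early list, which a deeper loss should lower, was at percentile 84.0 of those random lists, which decides neither way.

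For the mean amanitin response, 1 of 100 splits of the 12 arrays into 6 and 6, the real one, gave as many called probes with line as a covariate. The real split gave 11856 and the highest other 4639, of 462 possible splits. This argues against a chance split of these arrays. It cannot speak to chance between cultures, since the labels do not say whether replicates were separate cultures.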

How the results depend on the processing

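The offset of 50, the floor at the 60th percentile, the block with crossed tRNA-Glu 0 h numbers and the alternatives for gene lists were chosen after seeing the data. Values below are called probes, and the cause was not tested unless stated. Fits without tRNA-Glu 0 h replicate 2 left only replicate 1, the array that lay apart, in that group. Among fits with 1 array left out, they gave the highest counts for tRNA-Glu at 0 h and for stability. The deviation of that array cannot be told there from a line difference.

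The 4 amanitin counts stayed within 1.5 times under every alternative other than leaving out an array, but median scaling turned the balance to losses: 2118 higher and 7997 lower over the 3 lines. For tRNA-Glu at 0 h (203 in the report) the count was 382 without background correction, 385 with median scaling, 59 without a filter, 305 with probes above the floor on all arrays, 15 with only the groups compared, 48 with array weights, 748 for the mean of both times and 488 with the offset of 50. For tRNA-Arg at 0 h (161) it was 71 without a filter, 87 with only the groups compared, 260 with array weights, 646 for the mean of both times and 287 with the offset of 50. Between both tRNAs at 0 h (0) it was 1 without background correction, for the mean of both times and with the offset of 50.

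For tRNA-Glu stability (1) the count was 285 without background correction, 113 with median scaling (6 higher, 107 lower, the median of all probes being -0.13 in place of 0.01), 108 with the authors' processed values, 14 with probes above the floor on all arrays, 0 with array weights, 334 with the offset of 50 and 2 with the crossed block. For tRNA-Glu against tRNA-Arg stability (0) it was 1 with the offset of 50. Over the named probes and all alternatives, 431 values kept their side, 19 newly passed, 4 no longer passed and 0 reversed. ILMN_3268697 (log2 difference 2.94) no longer passed with array weights (2.94, adjusted p 0.0576) or without tRNA-Glu 0 h replicate 1 (2.81, 0.112), mock 9 h replicate 2 (2.72, 0.0502) or tRNA-Glu 9 h replicate 2 (2.84, 0.0734). Its adjusted p over all alternatives ranged from 0.000285 to 0.112.

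Leaving out 1 array at a time, with the lone array of a group assumed to vary like the other groups, gave 11245 to 12609 for the mean amanitin response, 4212 to 7843 in mock, 4150 to 8041 in tRNA-Arg and 5840 to 8153 in tRNA-Glu cells. At 0 h it gave 27 to 194 for tRNA-Arg, 38 to 2342 for tRNA-Glu and 0 to 1285 between both. For stability it gave 0 to 11 for tRNA-Arg, 0 to 2225 for tRNA-Glu and 0 to 575 between both.

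Of the 38 list medians, 18 were outside the random range, against 10 of 34 with the fixed lists as background. It was 16 without placeholder names, 16 with matched genes and 18 with means, and no list outside turned to the other side. With means 6 of the 18 were inside and 6 others, all for tRNA-Glu, were newly outside. The mean of probes per gene, the slide block, the estimated correlation and the median scaling of the gene lists were not run. Signal over background was not judged per array here, so how far it limits these counts is open.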

Other observations

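No test was run in this part. Of 3 common reference genes, chosen after their values were seen, GAPDH had -0.160 for tRNA-Glu and -0.0956 for tRNA-Arg, and ACTB -0.118 and -0.0945, in the authors' deposited table. EEF1A1 had 0.0702 and 0.0739 in the authors' deposited table.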
